A study of Mus musculus with 44 samples.

How the data were processed

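RNA was sequenced from 44 mouse libraries (strain C57BL/6) in 2 tables of values per gene. The in vivo table held 21 libraries of cells sorted from the spinal cord of injured mice. Of these, 13 were of microglia (3 at time 0 and 2 each at 1 h, 16 h, day 1, day 3 and day 7) and 8 of monocytes or the macrophages derived from them (2 each at 16 h, day 1, day 3 and day 7). Per the labels, the injury was a contusion of 200 kdyn after a laminectomy. The labels name no gate for the sort, and they list the time 0 mice as injured like the others, so whether those mice were uninjured is not given in the sources used here. The culture table held 23 libraries of cells under TGFb1 at 100 ng/ml. Of these, 11 were of macrophages grown from bone marrow with M-CSF and 12 of microglia from newborn mice, with 2 libraries each at 0, 1, 3, 6, 16 and 20 h except for 1 macrophage library at 6 h. No later untreated culture was in the tables. The time tag of 1 microglia library, 1 h replicate 2, reads 2 h where its title reads 1 h; the title was used. No label says whether replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries.

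Per the submitters' processing notes, reads were aligned with TopHat to the mouse build mm9. The TopHat version, the read counter, the gene annotation and the scaling method are not given in the sources used here. Both deposited tables hold a coverage signal per gene. Per library, 86.5% to 90.3% of the values of up to 20 reads (other than exactly 1) were whole multiples of a single step within a tolerance of 0.05 steps, and the others were fractions of it. The step was taken as the value of 1 read. No value was 0. A value of exactly 1 stood where no read was counted. The values were therefore read as counts that the authors had scaled by a factor per library. The plan written before the data were examined had allowed for counts or for normalized values. Since the unit turned out to be a signal with fractions, the plan's branch for normalized values was used and no count model was fitted. The tables were scaled separately, so no level was compared between them.

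The in vivo table had 8218 genes and that of the cultures had 12335, after a line that named no gene was left out (at most 0.0165% and 0.0140% of a library's total). Gene names were used as the tables give them. Of these, 7443 and 11112 matched a symbol of the reference list apart from upper case. Dividing each total by the step gave an estimate of the reads. It was 30505 to 185670 per in vivo microglia library, 132117 to 728109 per monocyte library, 1171520 to 1879800 per cultured macrophage library and 1746400 to 2249040 per cultured microglia library. The value of 1 read was 0.853 to 4.67 in the in vivo microglia and 0.170 to 0.850 in the monocytes, so in the latter a gene without reads was listed above a gene with 1 read. In the cultures it was 0.725 to 1.48.

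Values were fitted as log2(value + 1) with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, all groups of a table sharing an estimate of the spread, and an empirical Bayes step with trend and robust options. Genes needed a value of at least 1 in 2 or more libraries, a filter that every gene passed. The pseudocount makes the fold changes of low genes smaller than the ratio of their means. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. The median standard error of a log2 change was 0.819 for microglia against time 0, 0.897 for monocytes at day 7 against 16 h, 0.449 for monocytes against microglia and 1.27 for the difference of their changes. In culture it was 0.259 for TGFb1 against 0 h, 0.367 for the difference and 0.300 for the cell types at 0 h. Leaving out a library can leave a group with 1 library, which was then assumed to vary like the other groups.

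The 12 main comparisons, the 23 gene lists and the choice of named genes were written before the data were examined, as were the alternatives, apart from those said to have been added later. Lists covered 13 pathways or cell states (homeostatic microglia, infiltrating monocytes, proinflammatory genes, alternative activation, interferon response, TGFb response, cell cycle, MHC class II, lysosome with lipid and damage genes, cholesterol synthesis, matrix and proteases, glycolysis with hypoxia, and immediate early genes). The other 10 held markers of neutrophils, lymphocytes, dendritic cells, border macrophages, astrocytes, oligodendrocytes, neurons, endothelium, fibroblasts and erythroid cells. Each list with at least 5 measured members was tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of the contrast. Which lists the text describes was decided after their results were seen. Genes that rose or fell with TGFb1 in culture, at most 200 per direction with the smallest p first, were tested in the same way in the in vivo contrasts.

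Named genes followed a rule. First came the 6 largest rises and the 6 largest falls among called genes with a mean level above the median gene and every library of the higher side above every library of the other, leaving out predicted or unnamed genes. Where the text says that the libraries of these largest changes did not overlap, the rule had thus required it. For the differences of changes this separation is not defined. Next came up to 4 members of each described list, smallest p first. Irf7, Tgfb1, Tgfbr1, Tgfbr2, Cx3cr1 and Ccr2 could always be named. Some genes that the rule would name are not reported here. The neutrophil share of a library is the sum of the measured neutrophil markers as a percent of its total.

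The alternatives tried were quantile normalization, a filter of at least 10 in 2 libraries, no trend in the variance, pseudocounts of 0.1 and 5, fits of each cell type alone, replicate numbers as a block and leaving out each library in turn. After the data were seen, a filter on a mean of at least 20, array weights, a floor that set values below 5 to 5, the neutrophil share as a covariate in a fit of the microglia alone, the omission of 2 doubted microglia libraries and a block by column letters were added. Those 2 libraries were 1 h replicate 2, for its time tag, and day 3 replicate 2, which stood apart from the other libraries. The tests were tried on simulated values with 200 changed genes per comparison before use. In vivo, limma recovered 0 to 15% of genes changed 2-fold and 2 to 61% of those changed 4-fold. In culture these were 56 to 89% and 99 to 100%. The rates were not split by gene level, so they need not hold for low genes. False calls made up 0 to 14.3% of the calls in vivo, with 10.5% for microglia at 16 h, 10% at day 3 and 14.3% at day 7 (1 to 3 genes each), and 5.05 to 6.93% in culture. The simulation drew genes independently and gave each gene the same spread in all groups of a table. It therefore cannot show false calls that arise where a cell type varies more than the shared spread. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Every column of values was used.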

Results

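Sorted microglia, the resident macrophages of the spinal cord, were measured at time 0 and up to day 7 after a contusion injury. Monocyte-derived macrophages, called monocytes here, enter the injured cord from the blood and were measured from 16 h to day 7. In culture, macrophages from bone marrow and microglia from newborn mice were measured from 0 to 20 h under the cytokine TGFb1. Each group had 2 libraries, but for 3 of microglia at time 0 and 1 of cultured macrophages at 6 h. Between libraries of the same group, the Pearson correlation across genes was 0.51 to 0.78 for in vivo microglia, 0.80 to 0.93 for monocytes and 0.96 to 0.97 for the cultures. The in vivo microglia were the shallowest libraries, at 30505 to 185670 estimated reads. Of their genes 20.1 to 54.2% were listed at 1, the value that stands where no read was counted.

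The libraries labelled microglia held many transcripts of neutrophils, and those of the monocytes hardly any. S100a9, an abundant calcium-binding protein of neutrophils, stood at 9459 ± 532 (SD, n = 3) in microglia at time 0 and at 163 ± 56.6 (n = 2) in monocytes at day 7, where it was highest among the monocyte groups. The measured neutrophil markers made up 18.8% ± 3.08 of the total at time 0, 21.6% ± 1.24 at 1 h, 12.9% ± 2.33 at 16 h, 9.15% ± 1.93 at day 1, 10.5% ± 8.81 at day 3 and 14.6% ± 0.22 at day 7 (SD, n = 3 at time 0 and 2 at the other times). The 2 libraries of day 3 had 16.8% and 4.29%. Monocytes had 0.230% ± 0.00666 at 16 h, 0.207% ± 0.00789 at day 1, 0.278% ± 0.203 at day 3 and 0.488% ± 0.0648 at day 7 (SD, n = 2 each). The share counts only 11 marker genes, so any other RNA of neutrophils lies outside it, and the fraction of neutrophils was not estimated. Every microglia value reported here is that of such a mixture. Which of its cells carried a change was not tested.

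**Figure D1:**
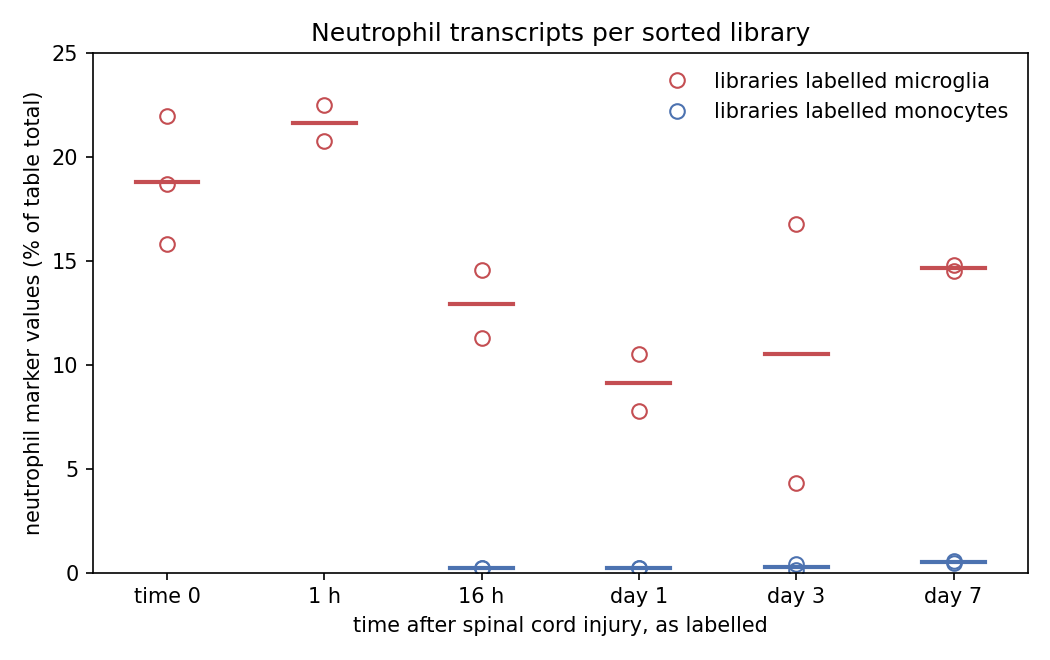
Neutrophil markers as a percent of the library total in the in vivo libraries, by cell type and time after injury, with a point per library and a line at each mean. Microglia libraries lie at 4.29% or more and monocyte libraries at 0.533% or less.

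The comparison of 1 h with time 0 asked how microglia first respond to the injury. Ccl4, a chemokine of activated microglia, rose from 2.38 ± 1.22 (SD, n = 3) to 81.1 ± 51.7 (n = 2), a 22.9-fold change (log2 4.52, SE 0.68, adjusted p = 0.00088). Nfkbia rose 7.82-fold from 46.4 ± 5.97 to 372 ± 80.3 (log2 2.97, SE 0.36, adjusted p = 3.7e-05). Apoe, a lipid carrier, fell 3.35-fold from 2772 ± 760 to 844 ± 345 (log2 -1.74, SE 0.24, adjusted p = 0.00021). The antigen-presenting genes H2-Aa (349 ± 34.7 to 91.6 ± 27.1, log2 -1.94, SE 0.33, adjusted p = 0.0050), H2-Ab1 (3.88-fold, adjusted p = 0.011) and Cd74 (2.96-fold, adjusted p = 0.027) fell as well. These 6 genes were all that passed, 2 up and 4 down, against 638 at an unadjusted p under 0.05. In each of them every library of the higher side lay above every library of the other.

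Of 13 measured MHC class II genes at 1 h, 3 fell and none rose (4 fell adjusted over the list alone). The group lay lower as a whole (camera, adjusted p = 1.2e-06, but adjusted p = 0.13 with an estimated correlation). H2-Eb1 stood at 50.2 ± 19.1 against 259 ± 190 and did not pass (adjusted p = 0.064). Among 22 proinflammatory genes 2 rose (4 adjusted over the list alone). The list lay higher (adjusted p = 0.0082, but adjusted p = 0.22 with an estimated correlation). Tnfaip3 was at 21.3 ± 1.27 against libraries listed at 1 (adjusted p = 0.18). Of 24 lysosome, lipid and damage genes Apoe alone fell (5 adjusted over the list alone, camera adjusted p = 0.0082, but adjusted p = 0.38 with an estimated correlation). Plin2 stood at 11.3 ± 3.87 against 59.6 ± 12.4 (adjusted p = 0.078). No member of the 18 immediate early genes (adjusted p = 0.72; 1 rose and 1 fell adjusted over the list alone), the 23 homeostatic genes (adjusted p = 0.39; 0 alone) or the 11 neutrophil markers (adjusted p = 0.27; 0 alone) passed. Dusp1 stood at 149 ± 73.3 against 50.1 ± 32.5 and C1qc at 49.3 ± 4.97 against 92.2 ± 7.02. The neutrophil share was 21.6% against 18.8%. Only Nfkbia kept its call whichever library was left out. Of the calls, 5 ended without 1 h replicate 1, 2 without time 0 replicate 3, and 1 each without 1 h replicate 2, time 0 replicate 1 or time 0 replicate 2. The 1 h replicate 1 had 0.290% erythroid RNA, against 0.00488 to 0.0107% at time 0. The total was 2 without 1 h replicate 1, 12 without time 0 replicate 1 and 10 without time 0 replicate 2. Quantile normalization ended the calls of Apoe and Cd74 and gave 3 rises and 2 falls (60% up, against 33.3%). Array weights ended all 4 falls, and a variance without a trend ended all calls but that of Ccl4, that of Nfkbia included. The calls of H2-Ab1, H2-Aa and Cd74 also ended without the 2 doubted libraries, and in a fit of the microglia alone with the neutrophil share as a covariate, though not in that fit without it.

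At 16 h the question was which genes microglia express as the first monocytes are measured beside them. Ccl4 rose 75.7-fold to 263 ± 146 (log2 6.24, SE 0.68, adjusted p = 4.6e-06). Cxcl2 rose 8.34-fold from 102 ± 78.2 to 803 ± 597 (log2 3.06, SE 0.48, adjusted p = 0.00073). Cd14 rose from 56.6 ± 31.2 to 350 ± 224 (log2 2.63, SE 0.49, adjusted p = 0.0071). The chemokines Ccl12 and Cxcl10 and the receptor chain Csf2rb2 rose 16.6- to 21.0-fold (adjusted p = 0.0071 to 0.023). The class II gene H2-Aa fell 3.84-fold to 93.5 ± 37.2 (log2 -1.94, SE 0.33, adjusted p = 0.0026). Of 57 called genes 44 rose and 13 fell (905 at an unadjusted p under 0.05).

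Of the 22 proinflammatory genes 5 rose at 16 h (11 adjusted over the list alone, camera adjusted p = 3.2e-09, and 0.014 with an estimated correlation), Nfkbia 5.60-fold to 276 ± 120. Among 31 interferon response genes 3 rose (5 adjusted over the list alone, adjusted p = 0.0021, but adjusted p = 0.28 with an estimated correlation). They were Cxcl10, Rsad2 (11.4 ± 11.3 to 125 ± 42.0, adjusted p = 0.030) and Oasl1, listed at 1 at time 0 and 28.3 ± 7.53 at 16 h (adjusted p = 0.035). Immediate early genes Ier3 (5.07-fold, adjusted p = 0.0081) and Dusp1 (4.75-fold, adjusted p = 0.035) rose, also adjusted over the list alone, without a shift of the list (adjusted p = 0.075). Of 13 class II genes 4 fell (1 rose and 4 fell adjusted over the list alone, adjusted p = 0.0057, but adjusted p = 0.38 with an estimated correlation). They were H2-Aa, Cd74 (704 ± 259 to 220 ± 62.6), H2-Ab1 and H2-Eb1. Falls also reached Mcm6, a replication helicase subunit (9.98-fold, adjusted p = 0.038), Ptms (5.77-fold, adjusted p = 0.026) and Hmgn5, listed at 1 in both libraries of 16 h against 28.0 ± 16.9. The homeostatic list did not pass (0 called, 1 rose adjusted over the list alone, adjusted p = 0.075), with Cst3 at 774 ± 258 against 388 ± 106 (adjusted p = 0.094). Nor did the neutrophil list (0 called, 0 alone, adjusted p = 0.70), at a neutrophil share of 12.9% against 18.8%. Of 19 named calls only that of Ccl4 held whichever library was left out. Without 16 h replicate 2, 18 ended (2 genes in total), 7 without 16 h replicate 1, and 5, 6 and 7 without time 0 replicates 1, 2 and 3. The 16 h replicate 2 had 0.346% erythroid RNA, against 0.00488 to 0.0107% at time 0. Array weights called 30 genes up and 0 down and ended 9 named calls, among them all 4 class II falls. A variance without a trend called 16 up and 3 down and ended 15, among them Ccl12, Cxcl10, Cd14, Nfkbia, Cxcl2, Ier3, Dusp1 and all 4 class II falls. In a fit of the microglia alone 12 of the 19 ended. With the neutrophil share as a covariate in that fit 4 more ended (Nfkbia, Cxcl2, Cd14 and Ier3), as their median absolute log2 change went from 2.56 (median SE 0.49) to 2.27 (0.53).

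Day 1 against time 0 asked how the response had developed. Ccl4 stood 85.9-fold higher at 275 ± 7.57 (log2 6.42, SE 0.68, adjusted p = 2.4e-06). The growth factor Csf1 rose 39.5-fold from 3.78 ± 4.82 to 142 ± 61.3 (log2 5.30, SE 0.92, adjusted p = 0.0024). The cytokine Il1b rose 6.61-fold from 100 ± 30.3 to 665 ± 227 (log2 2.72, SE 0.45, adjusted p = 0.0014). Ccrl2 was listed at 1 at time 0 and stood at 99.4 ± 35.3 (adjusted p = 0.00062). Lyz2, the myeloid lysozyme, fell 2.84-fold from 1541 ± 283 to 537 ± 30.5 (log2 -1.51, SE 0.23, adjusted p = 0.00061). In all, 62 genes rose and 13 fell (1039 at an unadjusted p under 0.05).

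Proinflammatory genes rose in 8 of 22 cases at day 1 (15 adjusted over the list alone, camera adjusted p = 9.1e-12, and 0.0059 with an estimated correlation). Among them were Nfkbia and Cxcl2, at 7.58- and 8.56-fold. Interferon response genes rose in 7 of 31 (16 adjusted over the list alone, adjusted p = 9.1e-12, and 0.011 with an estimated correlation). Ifit1 stood at 74.9 ± 60.2 against 1.77 ± 1.34 (adjusted p = 0.0064), Rsad2 20.3-fold and Isg15 12.2-fold higher. Irf7, a regulator of that response, was at 131 ± 36.8 against 38.4 ± 39.8 and did not pass (adjusted p = 0.090). Of 18 immediate early genes 3 rose (5 adjusted over the list alone, adjusted p = 3.0e-06, and 0.020 with an estimated correlation), Ier3 7.46-fold and Dusp1 4.57-fold, with Egr3 listed at 1 at time 0. Among the 24 lysosome, lipid and damage genes Csf1 rose and Apoe fell 2.03-fold to 1335 ± 39.6 (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.019, but adjusted p = 0.37 with an estimated correlation). Spp1 stood at 118 ± 52.3 against 26.0 ± 20.6 (adjusted p = 0.059). Of 27 infiltrating monocyte genes Lyz2 and Lyz1 fell (2 adjusted over the list alone). Their median and mean change were both 0.18 while the test pointed down (adjusted p = 0.88). Neutrophil markers passed in 0 of 11 (1 rose and 3 fell adjusted over the list alone, adjusted p = 0.063), at a share of 9.15% against 18.8%. Falls were also found for Tkt (4.04-fold, adjusted p = 0.030) and Maml1 (13.6-fold, adjusted p = 0.016), and rises for Gadd45b (27.3-fold, adjusted p = 0.0040). Of 22 named calls 7 held whichever library was left out (Ccl4, Nfkbia, Cxcl2, Ccrl2, Csf1, Ier3 and Lyz2). Without day 1 replicate 2, 14 ended (17 genes in total), 8 without day 1 replicate 1 and 5 without each of the time 0 replicates 1, 2 and 3. The day 1 replicate 2 had 0.440% erythroid RNA, against 0.00488 to 0.0107% at time 0. A variance without a trend called 35 up and 10 down and ended 8 named calls (Il1b, Rsad2, Dusp1, Apoe, Lyz1, Lyz2, Tkt and Rnaseh2c). Array weights called 31 up and 2 down and ended 7, among them Apoe, Lyz1, Tkt and Maml1. Apoe changed sign to 0.30 under quantile normalization. In a fit of the microglia alone 9 of the named calls ended, and with the neutrophil share as a covariate in that fit 12 more, as their median absolute log2 change went from 3.01 (median SE 0.49) to 2.51 (0.66). The ratio of the change with the covariate to that without it ran from 0.424 to 1.35 among these 12.

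By day 3 no gene passed against time 0 in limma, with 1176 at an unadjusted p under 0.05. The microglial genes Tmem119 (132 ± 74.7 against 20.3 ± 18.3, log2 3.32, SE 0.89, adjusted p = 0.099), Olfml3 (log2 4.08, SE 1.01, adjusted p = 0.094), Rtn4rl1 (32.0 ± 22.9 against 5.38 ± 7.59, adjusted p = 0.11) and C1qa (472 ± 270 against 153 ± 111, adjusted p = 0.12) had the smallest p among 23 homeostatic genes. This list lay higher (0 called, 12 rose adjusted over the list alone, camera adjusted p = 8.5e-07, but adjusted p = 0.47 with an estimated correlation). Ctsz, a lysosomal protease, was at 247 ± 156 against 64.4 ± 19.0 (adjusted p = 0.079). Axl, a receptor for dying cells, was at 25.1 ± 15.6 against libraries listed at 1 (adjusted p = 0.079). Their lysosome, lipid and damage list did not shift (0 called, 5 rose adjusted over the list alone, adjusted p = 0.16). The proinflammatory list lay higher (0 called, 5 rose adjusted over the list alone, adjusted p = 0.049, but adjusted p = 0.47 with an estimated correlation), with Nfkbia at 126 ± 49.0 (adjusted p = 0.099). Neutrophil markers lay lower (0 called, 0 alone, adjusted p = 0.049, but adjusted p = 0.62 with an estimated correlation), at shares of 16.8% and 4.29% in the 2 libraries. The count was 525 without day 3 replicate 1, 29 without day 3 replicate 2, 9 without time 0 replicate 1 and 56 without time 0 replicate 2.

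Day 7 against time 0 asked which changes were present in the late phase. Cst7 was listed at 1 at time 0 and stood at 28.8 ± 23.1 (adjusted p = 0.031). Dhrs1 rose 17.9-fold from 1.77 ± 1.34 to 45.4 ± 0.371 (log2 4.17, SE 0.92, adjusted p = 0.040), and Ms4a6d, a membrane protein of myeloid cells, 11.5-fold to 32.4 ± 24.6 (adjusted p = 0.035). Ezr fell 13.1-fold from 64.7 ± 13.4 to 6.14 ± 7.27 (log2 -3.71, SE 0.66, adjusted p = 0.013). The respiratory chain subunit Ndufv3 fell from 42.7 ± 25.6 to 2.58 ± 2.23 (adjusted p = 0.020). Of 36 called genes 24 rose and 12 fell (1284 at an unadjusted p under 0.05). Each named one had separate libraries, which the naming rule required of the largest changes.

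Of 24 lysosome, lipid and damage genes Cst7 alone passed at day 7 (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.059), with Ctsd at 1191 ± 76.1 against 524 ± 103 (adjusted p = 0.057). The homeostatic list lay higher (0 called, 5 rose adjusted over the list alone, adjusted p = 0.0041, but adjusted p = 0.97 with an estimated correlation). C1qa was at 445 ± 72.2 (adjusted p = 0.098) and Cx3cr1, the fractalkine receptor, at 99.5 ± 23.7 against 73.0 ± 47.5 (adjusted p = 0.56). Class II genes did not pass (0 called, 0 alone, adjusted p = 0.20), H2-Aa at 576 ± 169, nor did the neutrophil markers (0 called, 0 alone, adjusted p = 0.43) at a share of 14.6% against 18.8%. Ezr, Ndufv3 and Tubb6 were the 3 of 13 named calls that held whichever library was left out. Of the others 6 and 8 ended without day 7 replicates 1 and 2 (321 and 352 genes in total) and 4 each without time 0 replicates 1, 2 and 3 (51, 73 and 71 genes). All 13 ended with array weights and in a fit of the microglia alone, each of which called 0 genes, so that adding the neutrophil share to the latter could end no further call. Quantile normalization called 11 genes and ended 9 of the named calls, those of Dhrs1 and Ms4a6d among them.

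**Figure D2:**
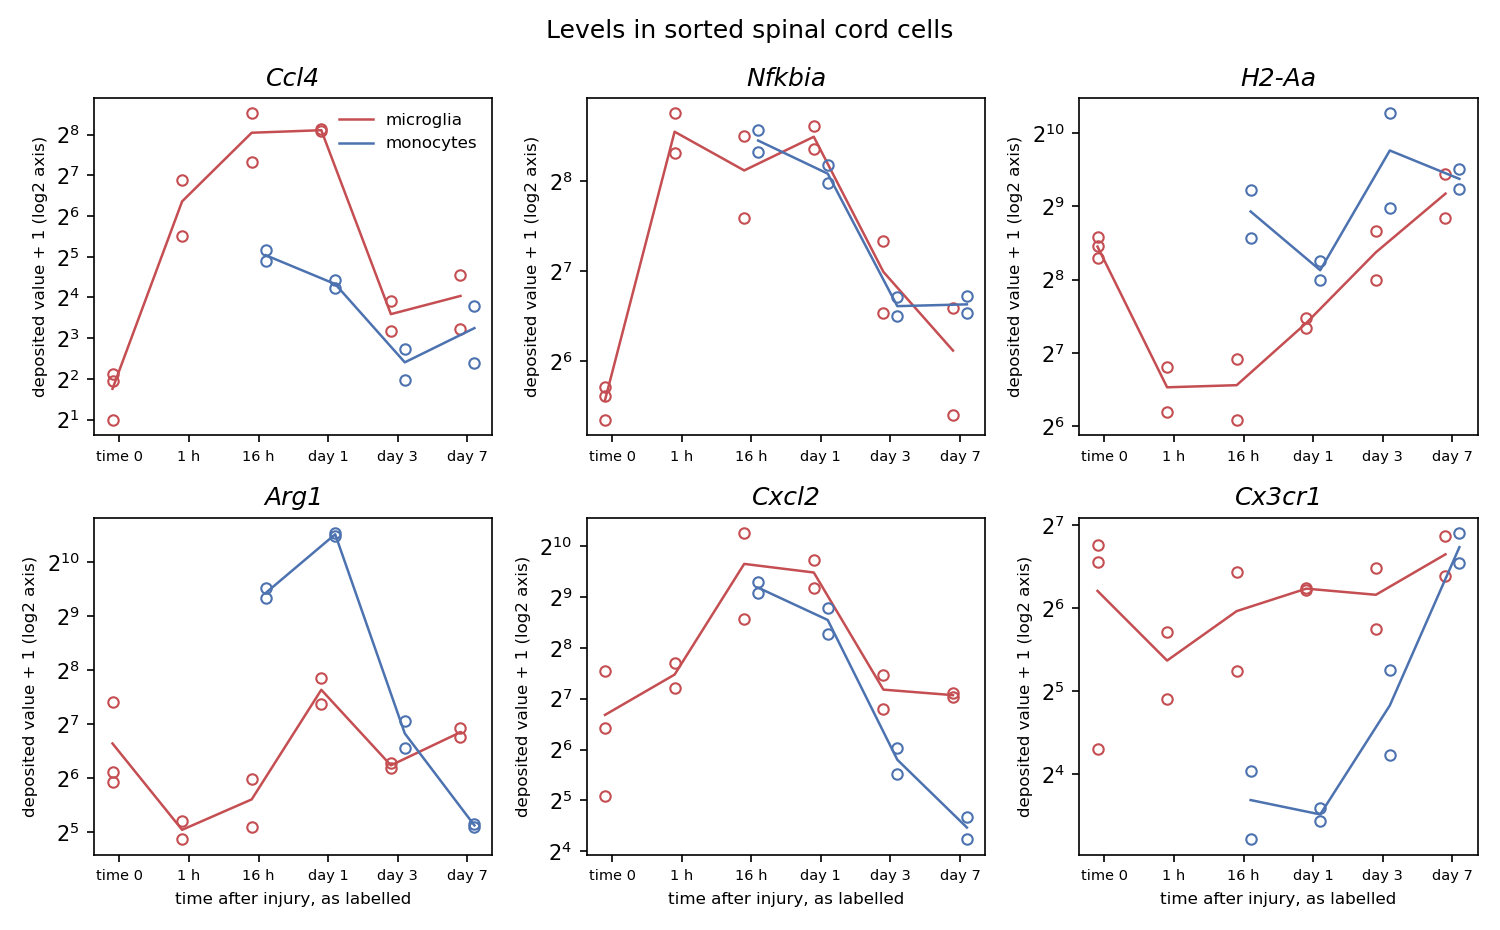
Values of 6 genes (value + 1, log2 axis) in the in vivo libraries against time after injury, with a point per library and lines through the means of microglia and of monocytes. Ccl4 in microglia lies at 263 ± 146 at 16 h and 275 ± 7.57 at day 1, and Arg1 in monocytes at 686 ± 60.5 at 16 h and 33.8 ± 0.97 at day 7.

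Monocytes at day 7 were set against 16 h to ask how cells change while they stay in the cord. The day 7 libraries were shallower, at 132117 to 152457 estimated reads against 542551 to 728109. Of their genes 16.4 to 18.5% were listed at 1, against 7.40 to 10.7% at 16 h. Whether depth added to the changes was not tested. Arg1, the arginase of alternatively activated macrophages, fell 19.7-fold from 686 ± 60.5 to 33.8 ± 0.97 (SD, n = 2 each, log2 -4.30, SE 0.42, adjusted p = 4.9e-07). The neutrophil chemokines Cxcl3 (37.9-fold, adjusted p = 1.8e-06) and Cxcl2 (580 ± 60.0 to 21.1 ± 4.62, 26.5-fold, adjusted p = 1.8e-06) and the matrix protein Thbs1 (1093 ± 86.1 to 81.6 ± 20.4, 13.4-fold, adjusted p = 4.0e-05) fell. Genes typical of microglia rose, Cx3cr1 8.58-fold from 11.8 ± 5.08 to 106 ± 19.1 (log2 3.10, SE 0.66, adjusted p = 0.017), C1qc 6.67-fold (adjusted p = 0.012) and C1qa 6.56-fold (adjusted p = 0.014). Apoe rose 3.89-fold from 642 ± 41.3 to 2551 ± 716 (log2 1.96, SE 0.26, adjusted p = 4.2e-05). Gpnmb rose 9.82-fold to 81.0 ± 50.9 (adjusted p = 0.017). Of 49 called genes 7 rose and 42 fell (525 at an unadjusted p under 0.05), which quantile normalization changed to 16 and 41 (28.1% up, against 14.3%). The named ones had every library of a time above those of the other, which the naming rule required of the largest changes.

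Proinflammatory genes fell in 6 of 22 cases (9 adjusted over the list alone, camera adjusted p = 6.6e-10, and 0.0040 with an estimated correlation). Il1b fell 10.4-fold from 569 ± 16.5 and Cd14 11.2-fold from 447 ± 145, and Nos2 was listed at 1 in both libraries of day 7 against 16.7 ± 0.338. In the 15 alternative activation genes 3 fell (4 adjusted over the list alone, adjusted p = 1.1e-06, and 0.0026 with an estimated correlation). Tgm2 fell 8.11-fold (adjusted p = 0.0065) and Il1rn 7.91-fold (adjusted p = 0.047) beside Arg1. Matrix and protease genes fell in 5 of 17 (2 rose and 6 fell adjusted over the list alone, adjusted p = 2.7e-05, but adjusted p = 0.052 with an estimated correlation). Among them were Adam8 (7.49-fold), Plaur (8.48-fold) and Mmp19 (8.35-fold). No glycolysis or hypoxia gene of 20 passed, yet the list lay lower (4 fell adjusted over the list alone, adjusted p = 2.4e-12, and 0.0019 with an estimated correlation). The glucose transporter Slc2a1 was at 23.4 ± 1.88 against 128 ± 9.52 (adjusted p = 0.10) and Vegfa at 6.12 ± 3.36 against 96.1 ± 2.60 (adjusted p = 0.12). Cell cycle genes lay higher (0 of 29 called, 1 rose adjusted over the list alone, adjusted p = 9.5e-09, but adjusted p = 0.060 with an estimated correlation). Aurka was at log2 3.17 (SE 0.89, adjusted p = 0.15) and Mki67 at 46.7 ± 44.8 against 5.04 ± 5.96 (adjusted p = 0.51). Of 23 homeostatic genes 3 rose (5 adjusted over the list alone, adjusted p = 6.6e-07, but adjusted p = 0.22 with an estimated correlation). Neutrophil markers lay higher too (0 of 11 called, 2 rose adjusted over the list alone, adjusted p = 0.0032, but adjusted p = 0.25 with an estimated correlation), at a share of 0.488% against 0.230%. Whether cells of the microglia sort, which carried such markers, added to these rises was not tested. Of 24 lysosome, lipid and damage genes Apoe, Ctsd and Gpnmb rose (5 rose and 2 fell adjusted over the list alone, adjusted p = 0.14). TGFb response genes lay lower (Id2 fell 4.13-fold, 2 fell adjusted over the list alone, adjusted p = 0.0061, but adjusted p = 0.060 with an estimated correlation). Ccr2 was at 203 ± 34.2 against 82.6 ± 26.2 (adjusted p = 0.83). Of 24 named calls 9 held whichever library was left out (Apoe, Sdc4, Cxcl3, Cxcl2, Il1b, Cd14, Arg1, Thbs1 and Adam8). The total was 19 and 13 without replicates 1 and 2 of 16 h and 14 and 20 without replicates 1 and 2 of day 7. A fit of the monocytes alone called 425 genes, 152 up and 273 down, and kept all 24. A variance without a trend called 0 genes up and 11 down and ended 15 of the 24. These were the rises of Gpnmb, Cx3cr1, C1qc, C1qa, Apoe, Ctsd and Hsp90ab1, thus every named rise, and the falls of Il1b, Cd14, Tgm2, Il1rn, Adam8, Plaur, Mmp19 and Id2.

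Monocytes against microglia, as the mean of 16 h, day 1, day 3 and day 7, asked what sets the entering cells apart from the resident ones. Of 11 neutrophil markers 10 were lower in monocytes (10 also adjusted over the list alone, camera adjusted p = 4.0e-31, and 0.0017 with an estimated correlation). Retnlg, a resistin-like protein of neutrophils, stood at 6.83 ± 5.73 against 762 ± 285 (SD, n = 8 each, 106-fold, adjusted p = 3.5e-17), and Lcn2 and Ltf were 28.0- and 79.6-fold lower. The complement genes C1qa (52.5 ± 37.3 against 343 ± 174, log2 -2.87, SE 0.28, adjusted p = 2.7e-08) and C1qc (6.34-fold, adjusted p = 7.7e-08) were lower in monocytes too. Fn1, fibronectin, was 3.91-fold higher in monocytes (488 ± 305 against 111 ± 38.1, adjusted p = 6.6e-06), Vim, vimentin, 2.76-fold (adjusted p = 3.7e-08) and Ccr2 as well (118 ± 58.8 against 29.5 ± 16.7, log2 2.00, SE 0.34, adjusted p = 0.00024). Ms4a4c, of the monocyte membrane, was 7.16-fold higher (31.5 ± 12.9 against 4.35 ± 4.37, adjusted p = 0.00016). The neutrophil share was 0.134 to 0.533% in the 8 monocyte libraries and 4.29 to 16.8% in the 8 microglia libraries. In all, 326 genes were higher in monocytes and 296 lower (1763 at an unadjusted p under 0.05). Of the genes named in this paragraph, Vim was the only one whose libraries overlapped between the cell types.

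Of 23 homeostatic genes 11 were lower in monocytes (13 adjusted over the list alone, adjusted p = 1.8e-13, but adjusted p = 0.095 with an estimated correlation), including Cx3cr1 at 38.8 ± 42.8 against 76.5 ± 23.9 (2.95-fold, adjusted p = 0.0027). Of 27 infiltrating monocyte genes 16 were higher and 2 lower (18 and 4 adjusted over the list alone, adjusted p = 2.4e-06, but adjusted p = 0.095 with an estimated correlation), with S100a10 5.68-fold higher and Ifitm6 4.84-fold lower. Class II genes were higher in 4 of 13 (5 adjusted over the list alone, adjusted p = 0.00084, but adjusted p = 0.15 with an estimated correlation), namely Cd74 2.25-fold, H2-Aa 2.23-fold, H2-Eb1 2.11-fold and Ctss 1.45-fold. Of 17 matrix and protease genes 5 were higher and 3 lower (8 and 3 adjusted over the list alone, adjusted p = 0.25). Mmp9, a neutrophil granule protease, was 34.7-fold and Mmp8 7.72-fold lower, against Thbs1 4.18-fold and Timp1 5.89-fold higher. Alternative activation genes were higher in 3 of 15 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.017, but adjusted p = 0.095 with an estimated correlation), Arg1 2.65-fold, Tgm2 2.72-fold and Klf4 2.91-fold. Of 24 lysosome, lipid and damage genes 6 were higher, such as the lectin Lgals3 (2.51-fold), and 6 lower, such as Csf1 (10.8-fold) and Ctsd (2.36-fold). Their median was 0.15 and their mean -0.03, with no shift (6 and 7 adjusted over the list alone, adjusted p = 0.63). Glycolysis and hypoxia genes Hif1a (4.27-fold), P4ha1 and Vegfa were higher (3 adjusted over the list alone, adjusted p = 0.011, but adjusted p = 0.15 with an estimated correlation). These are means over times that can differ. At day 7 Arg1 was lower in monocytes (33.8 ± 0.97 against 114 ± 8.79, log2 -1.72, SE 0.42, adjusted p = 0.041), and Cx3cr1 (106 ± 19.1 against 99.5 ± 23.7) and Tgm2 (log2 -0.10) did not pass. Tgfb1 itself was 2.41-fold higher in monocytes (72.6 ± 28.7 against 30.0 ± 12.5, log2 1.27, SE 0.27, adjusted p = 0.0029). Irf7 did not pass (67.3 ± 35.8 against 63.7 ± 47.2, adjusted p = 0.73). S100a10, Mmp9, Mmp8, Klf4 and Lgals3 had separate libraries, and those of the other genes named in this paragraph overlapped. Of 42 named calls 38 held whichever library was left out. Leaving out any of the 16 libraries except microglia day 7 replicate 2 ended at least 1 of the calls of Ctss, Klf4, P4ha1 and Vegfa. A variance without a trend ended 5 of the 42 (Cst3, H2-Eb1, Ctss, Klf4 and Vegfa). The total was 406 and 386 without replicates 1 and 2 of monocytes at 16 h, 400 without day 1 replicate 1, and 411 and 381 without replicates 1 and 2 of day 3. At single times the genes higher and lower in monocytes were 24 and 83 at 16 h, 12 and 46 at day 1, 25 and 50 at day 3 (45 and 54 under quantile normalization) and 18 and 58 at day 7 (43 and 71).

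Whether the change from 16 h to day 7 differed between the cell types was tested as a difference of changes, monocytes minus microglia. Arg1 was the only gene that passed (log2 difference -5.61, SE 0.60, adjusted p = 2.9e-06; 466 at an unadjusted p under 0.05). It fell in monocytes by 4.30 on the log2 scale and stood at 47.6 ± 20.7 at 16 h and 114 ± 8.79 at day 7 in microglia, where it did not pass (log2 1.31, SE 0.42, adjusted p = 0.16). It passed under every alternative and with every library left out, which gave 61 genes without microglia day 7 replicate 1, 29 without day 7 replicate 2 and 3 without 16 h replicate 2. Alternative activation genes had a mean difference of -0.94 (1 of 15 lower, 2 adjusted over the list alone, camera adjusted p = 0.00074, and 0.045 with an estimated correlation) and glycolysis and hypoxia genes of -1.03 (0 of 20 passed, 0 alone, adjusted p = 0.00010, and 0.046 with an estimated correlation). Interferon response genes had a median difference of 1.72 (0 of 31, 0 alone, adjusted p = 0.00010, but adjusted p = 0.13 with an estimated correlation), and class II genes a mean difference of -0.97 (0 of 13, 1 lower adjusted over the list alone, adjusted p = 0.00075, but adjusted p = 0.30 with an estimated correlation). Over the same interval microglia rose in 21 and fell in 42 genes (1105 at an unadjusted p under 0.05). H2-Aa was among those that rose (log2 2.64, SE 0.36, adjusted p = 0.00024), at neutrophil shares of 12.9% and 14.6% in microglia and 0.230% and 0.488% in monocytes.

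Cultured macrophages at 16 and 20 h under TGFb1 were set against 0 h to ask how cells of monocytic origin change under this cytokine. No untreated library after 0 h was available. TGFb1 and time in culture therefore cannot be told apart in any comparison of a later culture time with 0 h, differences of changes included. Pmepa1, a feedback inhibitor of TGFb signalling, rose 18.0-fold from 21.9 ± 1.52 (SD, n = 2) to 412 ± 32.8 (n = 4, log2 4.17, SE 0.09, adjusted p = 4.5e-17). Cx3cr1 rose 10.4-fold from 29.8 ± 2.79 to 323 ± 46.0 (log2 3.39, SE 0.08, adjusted p = 9.0e-17). The secreted matrix protein Tgfbi rose 5.66-fold from 513 ± 12.4 to 2918 ± 330 (adjusted p = 4.0e-12). Lpl, lipoprotein lipase, fell 3.29-fold from 6474 ± 353 to 1992 ± 384 (log2 -1.72, SE 0.05, adjusted p = 4.9e-15). Irf7 fell 2.45-fold from 740 ± 18.4 to 310 ± 83.1 (log2 -1.29, SE 0.26, adjusted p = 0.0016). In all 780 genes rose and 733 fell (3052 at an unadjusted p under 0.05), and the libraries of the 2 sides did not overlap for these 5. Other large changes were rises of X99384, F11r, Ctla2a and Nuak1 (7.38- to 11.1-fold) and falls of Stap1, Slc40a1, Plk2 and Flrt2 (3.19- to 3.77-fold).

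Of 23 homeostatic microglia genes 15 rose in the macrophages (18 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.8e-18, and 4.8e-05 with an estimated correlation). Fcrls rose 5.43-fold from 47.7 ± 5.17 and Olfml3 6.98-fold. TGFb response genes rose in 12 of 25 (14 rose and 1 fell adjusted over the list alone, adjusted p = 3.9e-12, and 5.4e-05 with an estimated correlation). They included Id1 (2.49-fold) and the receptor Tgfbr1 (2.15-fold). Tgfbr2 did not pass (log2 0.18, adjusted p = 0.51), nor did Tgfb1 (log2 -0.36, adjusted p = 0.067). Cell cycle genes rose in 16 of 35 and fell in 1 (21 and 1 adjusted over the list alone, adjusted p = 4.6e-08, and 0.00021 with an estimated correlation). Ube2c rose 3.15-fold from 64.5 ± 8.29 (adjusted p = 6.1e-06) and Rrm2 2.09-fold. Of 25 lysosome, lipid and damage genes 4 rose and 13 fell (5 and 13 adjusted over the list alone, adjusted p = 2.7e-07, and 0.0043 with an estimated correlation), Lgals3 1.76-fold and Plin2 1.92-fold. Cholesterol synthesis genes rose in 6 of 19 (11 adjusted over the list alone, adjusted p = 8.6e-05, and 0.0038 with an estimated correlation), among them Insig1 1.76-fold. Glycolysis and hypoxia genes rose in 9 of 20 and fell in 1 (11 and 2 adjusted over the list alone, adjusted p = 0.00035, and 0.023 with an estimated correlation), Bnip3 2.91-fold and P4ha1 1.86-fold. Immediate early genes fell in 10 of 19 and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 4.7e-05, and 0.0043 with an estimated correlation), Egr2 3.96-fold and Atf3 1.92-fold. Of 32 interferon response genes 4 fell (4 adjusted over the list alone, adjusted p = 0.27), Bst2 1.34-fold beside Irf7. Quantile normalization ended the calls of Bst2 and Oas1a. Of 26 infiltrating monocyte genes 6 rose and 3 fell (6 and 3 adjusted over the list alone). Their median was -0.12 and their mean -0.09, while the test pointed up (adjusted p = 0.93). Of 45 named calls 40 held whichever library was left out. Without 0 h replicate b the calls of Acat2, Insig1, Ifi204 and Oas1a ended, without 0 h replicate a those of Idi1, Ifi204 and Oas1a. Without 16 h replicate b that of Idi1 ended, and without 16 h replicate a or 20 h replicate a those of Ifi204 and Oas1a. A fit of the macrophages alone called 712 genes and ended 10 named calls, among them Slc40a1, Flrt2, Insig1, P4ha1 and Egr2. With replicate numbers as a block in that fit 12 ended, among them Bnip3, Slc2a1 and Fos, which the fit without the block had kept.

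Cultured microglia at 16 and 20 h against 0 h asked the same of resident cells. Gatm, which makes the creatine precursor, rose 2.60-fold from 241 ± 15.3 (SD, n = 2) to 629 ± 60.6 (n = 4, log2 1.38, SE 0.11, adjusted p = 9.7e-08). Tgfbi rose 2.48-fold (adjusted p = 2.5e-07) and Pmepa1 2.44-fold from 260 ± 26.4 to 635 ± 39.2 (log2 1.29, SE 0.09, adjusted p = 2.5e-08). The chemokine Ccl9 fell 4.22-fold from 155 ± 4.19 to 36.9 ± 8.80 (log2 -2.08, SE 0.12, adjusted p = 1.3e-09). Further falls were those of the mannose receptor Mrc1 (log2 -1.69, SE 0.19, adjusted p = 1.7e-05) and the lectin Clec4a2 3.89-fold (adjusted p = 1.8e-06). Irf7 fell 2.01-fold from 48.7 ± 1.94 to 23.8 ± 1.69 (adjusted p = 0.034). In all 185 genes rose and 186 fell (1436 at an unadjusted p under 0.05), and for these 7 genes the libraries of the 2 sides did not overlap.

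Of 23 homeostatic genes 6 rose in microglia (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.6e-08, and 0.0012 with an estimated correlation). Fcrls rose 1.86-fold and Cx3cr1 1.26-fold from 1904 ± 124 to 2390 ± 41.5 (adjusted p = 0.021). TGFb response genes rose in 5 of 25 (8 rose and 1 fell adjusted over the list alone, adjusted p = 0.00011, and 0.0034 with an estimated correlation), among them Tgfbr1 1.46-fold. Cell cycle genes fell in 7 of 35 (14 adjusted over the list alone, adjusted p = 1.6e-11, and 8.4e-05 with an estimated correlation). Top2a fell 2.23-fold from 99.0 ± 5.61 to 44.5 ± 9.03 (log2 -1.16, SE 0.17, adjusted p = 0.00035), Ube2c 2.29-fold, Plk1 2.96-fold and Birc5 2.04-fold. Of 25 lysosome, lipid and damage genes 8 rose and 4 fell (9 and 4 adjusted over the list alone, adjusted p = 0.024, but adjusted p = 0.15 with an estimated correlation). Ctsd rose 1.53-fold, and Lpl fell 1.63-fold and Clec7a 1.58-fold. Alternative activation genes fell in 3 of 17 (4 adjusted over the list alone, median change 0.00, mean -0.24, adjusted p = 0.0034, and 0.022 with an estimated correlation). Beside Mrc1 these were the scavenger receptors Cd36 (2.28-fold) and Msr1 (1.48-fold). Proinflammatory genes fell in 4 of 24 (5 adjusted over the list alone, adjusted p = 0.012, but adjusted p = 0.051 with an estimated correlation), Ccl3 1.57-fold and Ccl4 1.41-fold. Interferon response genes lay lower (Bst2 rose 1.29-fold and Irf7 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.0090, but adjusted p = 0.31 with an estimated correlation). Astrocyte markers lay higher (0 of 8 called, 4 rose adjusted over the list alone, adjusted p = 0.017, but adjusted p = 0.051 with an estimated correlation), with Gfap at 29.4 ± 7.57 and no call (adjusted p = 0.056). Of 34 named calls 19 held whichever library was left out. Of the others 11 each ended without 0 h replicate 1 (174 genes in total) and 0 h replicate 2 (166), 5 without 16 h replicate 1 and 4 each without 16 h replicate 2, 20 h replicate 1 and 20 h replicate 2. The 15 included Angptl2, Ch25h, Rai14, Plk1, Cx3cr1, Tgfbr1, Ski, Birc5, Msr1, Cd14, Ccl4, Ccl2, Bst2 and Irf7. Quantile normalization also ended the call of Cx3cr1. A variance without a trend called 156 genes up and 106 down and ended 12 named calls (Angptl2, Rai14, Cst3, Cx3cr1, Tgfbr1, Ski, Tyrobp, Cd14, Ccl4, Ccl2, Bst2 and Irf7).

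**Figure D3:**
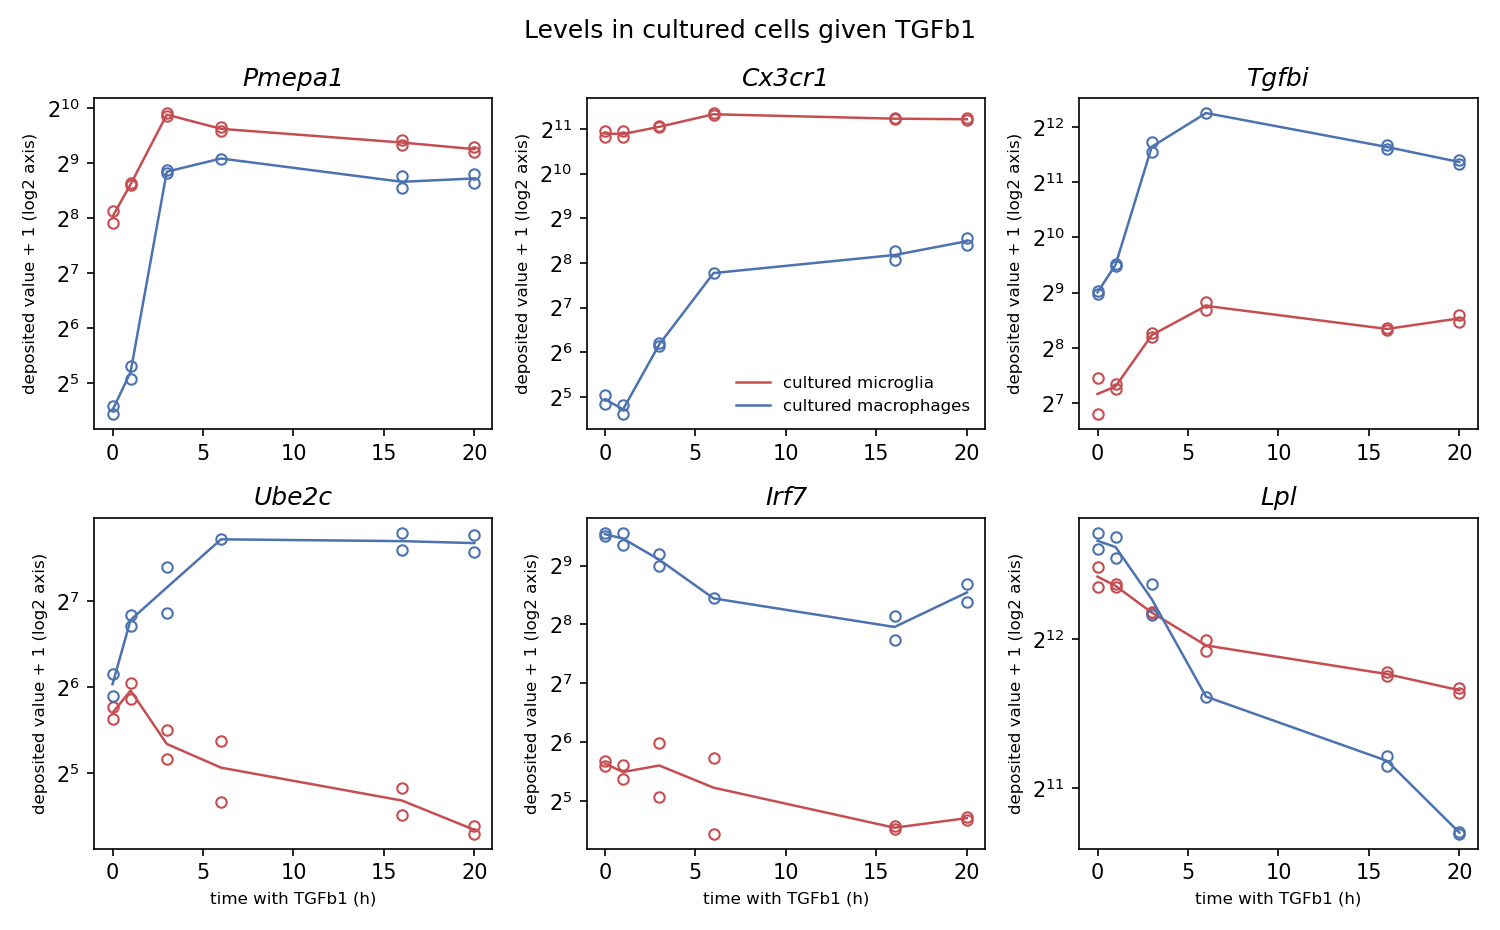
Values of 6 genes (value + 1, log2 axis) in cultured macrophages and microglia against hours of TGFb1, with a point per library and lines through the means. Cx3cr1 in macrophages climbs from 29.8 ± 2.79 at 0 h to 358 ± 26.1 at 20 h and stays below the 1904 ± 124 of microglia at 0 h, while Ube2c ends at 203 ± 19.4 in macrophages and 19.2 ± 0.840 in microglia.

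Whether the change under TGFb1 differed between the 2 cultured cell types was tested as macrophage change minus microglia change. Cx3cr1 rose by 3.06 log2 units more in macrophages (SE 0.11, adjusted p = 8.4e-13) and Pmepa1 by 2.88 (SE 0.13, adjusted p = 1.5e-11). Ube2c, which rose in macrophages and fell in microglia, differed by 2.85 (SE 0.28, adjusted p = 4.0e-06). The receptor Tgfbr1 rose by 0.56 more (SE 0.15, adjusted p = 0.032). Irf7, which fell in both, did not differ by the test (log2 -0.29, SE 0.36, adjusted p = 0.77), nor did Tgfbr2 (log2 0.01, adjusted p = 0.99). The difference was positive for 307 genes and negative for 233 (2034 at an unadjusted p under 0.05), with Ednrb (-2.35), Tspan13 (-2.07) and Flrt2 (-1.85) among the most negative.

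Cell cycle genes differed in 17 of 35, all toward macrophages (22 adjusted over the list alone, mean 1.16, camera adjusted p = 9.5e-19, and 7.3e-06 with an estimated correlation), Birc5 by 2.09 and Top2a by 1.68. Homeostatic genes differed upward in 8 of 23 and downward in 1 (12 and 1 adjusted over the list alone, mean 0.68, adjusted p = 2.6e-11, and 0.00021 with an estimated correlation), Fcrls by 1.55 and C1qc by 0.48. TGFb response genes differed upward in 8 of 25 (9 and 1 adjusted over the list alone, mean 0.55, adjusted p = 2.9e-07, and 0.00039 with an estimated correlation), Id1 by 1.45 and Id3 by 1.41. Of 25 lysosome, lipid and damage genes 14 differed downward and 1 upward (17 and 2 adjusted over the list alone, mean -0.30, adjusted p = 7.1e-16, and 0.00021 with an estimated correlation), Lpl by -1.01 and Gpnmb by -0.61. The call of Ctsb, at -0.42, ended under quantile normalization. Alternative activation genes differed upward in 6 of 17 (6 and 1 adjusted over the list alone, mean 0.32, adjusted p = 0.0064, and 0.026 with an estimated correlation), Tgm2 by 1.28 and Msr1 by 1.15. Of 30 named calls 24 held whichever library was left out. Leaving out any library of 0, 16 or 20 h, except replicate b of the macrophages at 16 or 20 h, ended the call of Tgfbr1, that of Flrt2 or both. F11r was lost without macrophage 0 h replicate b or microglia 0 h replicate 2, Tmem158 without the former, Il4ra without the latter and GYK without microglia 0 h replicate 1. The total was 317 and 309 without replicates 1 and 2 of microglia at 0 h. A variance without a trend called 192 positive and 135 negative differences and ended 5 named calls (F11r, Flrt2, C1qc, Ctsb and Tgfbr1).

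Among genes called in both cultures most moved the same way, while over all genes the Pearson correlation of the log2 changes was only 0.16. In both, 75 rose (11.7 by chance, 13 opposite, Fisher's exact test, 2-sided, p = 6.17e-42) and 104 fell (11.1 by chance, 9 opposite, p = 4.72e-79). This test treats genes as independent. Of these 179 genes 61 differed in the size of the change. In the fit that shares the spread between the cell types, the single times called 256 genes up and 115 down at 1 h, 735 and 594 at 3 h, 605 and 542 at 16 h and 746 and 726 at 20 h in macrophages, against 30 and 12, 51 and 32, 103 and 124, and 130 and 140 in microglia. The larger count of macrophages depends on that shared spread, since fits of each cell type alone called 712 and 691 genes at 16 and 20 h against 0 h. At 6 h the counts were 646 and 767 in macrophages and 64 and 88 in microglia, with 1 macrophage library whose spread was taken from the other groups.

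At 0 h, taken as before TGFb1, macrophages were set against microglia to ask how far the cultured cell types differ at the start. S100a4, a calcium-binding protein of motile cells, was 462-fold higher in macrophages (13136 ± 8.83 against 27.5 ± 3.04, SD, n = 2 each, log2 8.85, SE 0.16, adjusted p = 2.7e-19). Cd74 was 87.2-fold higher (1587 ± 15.4 against 17.3 ± 1.83, adjusted p = 5.1e-11). Irf7 was 14.9-fold higher in macrophages (740 ± 18.4 against 48.7 ± 1.94, log2 3.90, SE 0.30, adjusted p = 1.1e-09). Cx3cr1 was 61.8-fold lower (29.8 ± 2.79 against 1904 ± 124, log2 -5.95, SE 0.09, adjusted p = 1.1e-20), Pmepa1 11.4-fold lower (adjusted p = 6.2e-16) and Tgfbr2 2.76-fold lower (109 ± 34.8 against 294 ± 3.68, adjusted p = 5.9e-07). Ncan (1903 ± 216), Nnat (1171 ± 3.18) and Ptn (870 ± 20.5), genes of neural cells and their precursors, were in the microglia cultures and listed at 1 in the macrophages. Of 6301 called genes 2648 were higher in macrophages and 3653 lower (6944 at an unadjusted p under 0.05), and the libraries of the named genes did not overlap. The excess of lower genes depends on the scaling, since quantile normalization gave 3115 higher and 3061 lower (50.4% higher, against 42.0%).

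Homeostatic genes were lower in macrophages in 16 of 23 and higher in 5 (the same adjusted over the list alone, camera adjusted p = 9.3e-06, and 0.0031 with an estimated correlation), Fcrls 27.8-fold. Infiltrating monocyte genes were higher in 22 of 26 and lower in 4 (the same adjusted over the list alone, adjusted p = 1.1e-11, and 6.8e-05 with an estimated correlation), S100a6 47.3-fold. Interferon response genes were higher in 29 of 32 (30 adjusted over the list alone, adjusted p = 3.9e-13, and 0.0089 with an estimated correlation), Oasl2 12.9-fold. Class II genes were higher in 10 of 12 and lower in 1 (the same adjusted over the list alone, adjusted p = 1.8e-06, and 0.0040 with an estimated correlation), H2-Aa 243-fold. TGFb response genes were lower in 17 of 25 and higher in 2 (17 and 3 adjusted over the list alone, adjusted p = 0.00022, and 0.0035 with an estimated correlation), Smad7 9.32-fold and Id1 4.80-fold. Cholesterol synthesis genes were lower in 14 of 19 (14 adjusted over the list alone, adjusted p = 0.00035, and 0.0045 with an estimated correlation), Sqle 3.12-fold. Cell cycle genes were higher in 29 of 35 (29 adjusted over the list alone, adjusted p = 4.4e-12, and 6.8e-05 with an estimated correlation), Mcm5 11.4-fold and Mcm3 6.12-fold. Astrocyte markers were lower in 6 of 8 (6 adjusted over the list alone, adjusted p = 0.0012, and 0.010 with an estimated correlation). Neuron markers were lower in 6 of 6 (6 adjusted over the list alone, adjusted p = 0.00023, and 0.015 with an estimated correlation). Sparcl1 stood at 304 ± 11.3 and Gap43 at 111 ± 19.4 in the microglia cultures. Neutrophil markers were higher in macrophages in 6 of 8 and lower in 2 (the same adjusted over the list alone, adjusted p = 0.0018, and 0.015 with an estimated correlation), S100a9 at 160 ± 5.15. No named call was lost when a library was left out.

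Genes that changed with TGFb1 in culture were followed in the injured cord to ask whether their levels moved there. The 2 tables were normalized separately and share no library. Genes that fell in cultured microglia (165 of 186 measured in vivo) lay higher in microglia at 16 h (8 rose and 1 fell, camera adjusted p = 0.0032, but adjusted p = 0.052 with an estimated correlation). They lay higher at day 1 as well (8 rose, 0 fell, adjusted p = 0.0029, and 0.0496 with an estimated correlation), at neutrophil shares of 12.9% and 9.15% against 18.8% at time 0. They lay lower in monocytes at day 7 than at 16 h (9 fell, 0 rose, adjusted p = 0.0048, but adjusted p = 0.062 with an estimated correlation), and higher in monocytes than in microglia (31 higher, 5 lower, adjusted p = 8.0e-05, and 0.012 with an estimated correlation). Genes that fell in cultured macrophages (173 of 200) lay higher in microglia at day 1 (5 rose, 0 fell, adjusted p = 0.0029, but adjusted p = 0.11 with an estimated correlation) and in monocytes against microglia (20 higher, 4 lower, adjusted p = 0.00041, but adjusted p = 0.057 with an estimated correlation). Genes that rose in cultured microglia (135 of 185) lay lower at 1 h (0 called, adjusted p = 0.031, but adjusted p = 0.52 with an estimated correlation). No other of the 28 tests passed, including each of those on the genes that rose in macrophages (175 of 200 measured in vivo).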

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

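What drew attention to these results is a change that differed between cell types. The tests of the cell cycle pattern were written before their results were seen, whereas the lists given here were picked after theirs were seen. In vivo, the change from 16 h to day 7 differed between monocytes and microglia for 1 gene, Arg1, by -5.61 on the log2 scale. The mean difference was -0.94 for the alternative activation genes, which include Arg1, and -1.03 for the glycolysis and hypoxia genes. The former were not tested without Arg1. In monocytes these lists changed by a mean of -1.07 and -1.48, and in microglia by -0.13 (camera adjusted p = 0.97) and -0.45 (adjusted p = 0.41), where neither passed.

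In culture, the change under TGFb1 differed between macrophages and microglia for 540 genes. The mean difference, macrophages minus microglia, was 1.16 for the cell cycle genes, 0.68 for the homeostatic microglia genes, 0.55 for the TGFb response genes and 0.32 for the alternative activation genes. It was 0.37 for the cholesterol synthesis genes (2 of 19 differed upward, 2 adjusted over the list alone, camera adjusted p = 0.0011, and 0.0086 with an estimated correlation). It was -0.30 for the lysosome, lipid and damage genes. The infiltrating monocyte genes had 0.0789 (5 of 26 upward and 1 downward, adjusted p = 0.024, and 0.044 with an estimated correlation) and the immediate early genes -0.32 (1 of 19 downward, adjusted p = 0.013, and 0.048 with an estimated correlation).

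Cell cycle genes fell in cultured microglia under TGFb1, and 3 technical explanations were weighed, of which time in culture had no test. Oligodendrocyte precursors divide in such cultures, and a loss of them could lower these genes, but 13 of their markers had a median log2 change of 0.052 (SE 0.24) against -0.54 for the cell cycle list, with Pdgfra lower by 1.27 and Cspg4, C1ql1 and Ncan higher by 0.89, 1.40 and 0.58. This explanation and the fall within microglia cannot be told apart. Scaling between libraries was excluded, since 7 of the 7 called genes were also lower under quantile normalization. Time in culture and TGFb1 cannot be told apart, because 0 untreated libraries after 0 h were in the tables.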

How the results depend on the processing

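The alternatives and the leaving out of single libraries tested 450 values of 233 named genes, of which 290 were called. Over the planned and added settings the called values stayed called 2821 times, lost the call 309 times and changed sign once, Apoe in microglia at day 1, to 0.30 under quantile normalization. With a library left out they stayed 1846 times and lost the call 280 times. Alternatives not named below for a comparison moved its count by at most 1.5 times. A filter on any value above 0 removes no gene and gave nothing to compare, and alternatives that need counts were not run. Depth limits the in vivo microglia most, where 1 read is worth up to 4.67. Where no cause is given, the cause was not tested.

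In microglia against time 0 the calls depended on the setting. At 1 h (6 genes) there were 1 without a trend, 2 with array weights, 14 with the floor, 3 without the 2 doubted libraries and 3 with the neutrophil share as a covariate (a fit of the microglia alone throughout), and 2 to 12 with a library left out. At 16 h (57) there were 19 without a trend, 30 with array weights, 12 in microglia alone and 5 with the covariate, and 2 to 75 with a library left out. At day 1 (75) these were 45, 33, 24 and 1, and 17 to 109. At day 3 (0, limma, 1176 at an unadjusted p under 0.05) there were 26 without a trend, 17 with a pseudocount of 5, 4 with a mean of at least 20, 41 with the floor and 26 without the doubted libraries, and 0 to 525 with a library left out. At day 7 (36) there were 11 under quantile normalization, 73 without a trend, 9 with a mean of at least 20, 68 with the floor, 73 without the doubted libraries and 0 each with array weights, in microglia alone and with the covariate, and 51 to 352 with a library left out. A filter on the mean leaves 1220 genes to test. In the in vivo fits of a cell type alone, microglia take on their own larger spread and monocytes their smaller one.

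Monocytes at day 7 against 16 h (49) had 11 without a trend, 82 with a mean of at least 20, 614 with array weights and 425 in monocytes alone, and 13 to 20 with a library left out. Monocytes against microglia (622) had 406 with a mean of at least 20 and 381 to 837 with a library left out. The difference of their changes (1) had 3 without a trend, 2 with a pseudocount of 5, 3 with a mean of at least 20, 4 with array weights, 2 with the floor and 4 without the doubted libraries, and 1 to 61 with a library left out. Quantile normalization moved the median change of all genes from 0.06 to -0.06 in microglia at 16 h, from 0.14 to 0.03 in the difference and from -0.13 to 0.03 between the cultures at 0 h.

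Cultured macrophages (1513) had 712 in a fit of macrophages alone and 1068 to 1530 with a library left out. Cultured microglia (371) had 608 with array weights and 691 in microglia alone, and 166 to 294 with a library left out. The culture difference (540) had 327 without a trend and 309 to 540 with a library left out. At 0 h (6301) the count stayed between 4651 and 6338, and 5117 to 5538 with a library left out. Of 83 list tests that passed, 43 did with an estimated correlation. Of 7 tests of TGFb1 genes in vivo, 7 passed with all called genes and 2 with an estimated correlation.

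Replicate numbers did not pair the libraries. After group means were taken out, libraries of the same number correlated by -0.0249 to 0.0645 in in vivo microglia, -0.00545 to 0.0174 in monocytes and -0.0138 to 0.0289 in cultured macrophages, and by the letters of the microglia culture columns by -0.0477 to 0.0517. With the numbers as a replicate block the counts were 4 at 1 h, 71 at 16 h, 107 at day 1, 0 at day 3 (limma, 1176 at an unadjusted p under 0.05 without the block) and 63 at day 7, 52 for monocytes, 736 for monocytes against microglia and 1 for the difference. Only time 0 had a replicate 3, so the block fits that library exactly and in effect drops it. Without time 0 replicate 3 the counts against time 0 were 4, 71, 109, 0 and 71. The block counts against time 0 are therefore no separate check of pairing. In fits of a cultured cell type alone, which called 712 genes in macrophages and 691 in microglia, the block gave 594 in macrophages and that of the column letters 706 in microglia.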

Other observations

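Monocytes changed in gene groups before day 7. At day 3 the lysosomal protease Ctsb stood at 617 ± 91.6 against 129 ± 17.1 at 16 h (SD, n = 2 each, log2 2.25, SE 0.37, limma adjusted p = 0.0032), and Ctsd and Gpnmb had risen too (log2 1.65 and 3.51, SE 0.32 and 0.71, limma adjusted p = 0.022 and 0.027). The lysosome, lipid and damage genes lay higher at day 3 (3 of 24 rose, 4 adjusted over the list alone, camera adjusted p = 8.4e-12, and 0.010 with an estimated correlation). Spp1, osteopontin, was at 452 ± 113 against 48.4 ± 4.57 and did not pass (limma adjusted p = 0.11). Proinflammatory genes already fell by then (4 of 22, 7 adjusted over the list alone, camera adjusted p = 7.4e-12, and 0.0034 with an estimated correlation). At day 1 no gene was called against 16 h by limma (114 at an unadjusted p under 0.05), while the interferon response genes lay higher as a group (0 of 31 called, 0 alone, median log2 change 1.08, camera adjusted p = 2.2e-12, and 0.016 with an estimated correlation). Irf7 was at 31.6 ± 2.66 at 16 h, 92.3 ± 28.5 at day 1 and 85.9 ± 59.5 at day 3.

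Cultured macrophages changed within 1 h of adding TGFb1, a comparison that has no untreated control and so cannot part TGFb1 from the handling or time in culture. At 1 h Egr1 stood at 250.2 ± 16.0 against 13.1 ± 9.21 at 0 h (SD, n = 2 each, log2 4.33, SE 0.61, limma adjusted p = 0.00015) and at 3 h it did not pass against 0 h (limma adjusted p = 0.54). Fos rose from 151 ± 2.30 to 585 ± 110.2 at 1 h (log2 1.93, SE 0.19, limma adjusted p = 1.1e-06). Of 19 immediate early genes 15 rose in macrophages at 1 h (16 adjusted over the list alone, camera adjusted p = 6.4e-43, and 6.0e-07 with an estimated correlation) and 2 in microglia (8 adjusted over the list alone, adjusted p = 8.3e-12, and 0.00025 with an estimated correlation). Whether the 1 h changes differ between the cell types was not tested. Pmepa1 went in macrophages from 21.9 ± 1.52 to 36.0 ± 4.17 at 1 h and 458 ± 12.9 at 3 h. Cx3cr1 was slower, at 25.4 ± 2.57 at 1 h, 71.4 ± 2.52 at 3 h and 289 ± 29.4 at 16 h. Interferon response genes fell in macrophages at 3 h (9 of 32, 11 adjusted over the list alone, adjusted p = 4.9e-06, but adjusted p = 0.085 with an estimated correlation).

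All tests of the neutrophil pattern were chosen after it had been seen. Of the 11 measured markers 10 were higher in each of the 13 microglia libraries than in each of the 8 monocyte libraries. Since these markers define the pattern, neutrophils among the sorted cells and neutrophil RNA carried over from elsewhere cannot be told apart, and no biological explanation was tested. Lower depth does not account for it, because the mean share in microglia at 16 h was 26.5 times that in monocytes at day 7, where depth was alike. A swap of single libraries between the cell types would leave a partner out of place, but 0 monocyte libraries reached the lowest microglia share, and an exchange of both labels as a whole, which would give 0 as well, is argued against by C1qa, C1qc and Sparc, 7.29-, 6.34- and 23.7-fold higher in the microglia libraries, and by Ccr2, Fn1 and Ms4a4c, higher in those of the monocytes.

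Of 13 class II genes 3 fell in microglia at 1 h and 4 at 16 h, without a shift of the list with an estimated correlation (adjusted p = 0.13 and 0.38), array weights and a variance without a trend each ended all of these calls, and the tests of dilution and the covariate were chosen after this was seen while those of depth were not. Dilution by neutrophil RNA would lower all microglial genes alike, but the homeostatic list had a median of -0.28 at 1 h (SD of members 0.785, n = 23) against a mean of -1.91 for 4 class II genes, and the neutrophil share at 16 h lay 5.89 points lower than at time 0 (a change of -5.89). In a fit of the microglia alone the calls of H2-Ab1 and H2-Eb1 at 16 h ended without any covariate (-1.64 and -2.10, SE 0.38 and 0.52), while those of H2-Aa, H2-Ab1 and Cd74 at 1 h ended only once the share joined that fit, which moved them from -1.94, -1.96 and -1.57 (SE 0.37, 0.38 and 0.32) to -1.89, -1.87 and -1.48 (SE 0.34, 0.38 and 0.31), and why their adjusted p rose was not tested. With microglia libraries thinned to 30604 reads, these genes had means of -1.89 at 1 h and -1.88 at 16 h (medians of 20 draws). The draws ranged from -2.16 to -1.80 and -2.07 to -1.62. Thinning hardly moves genes of this level, so depth was not excluded. No biological explanation was tested.

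A further hypothesis, written before its test, held that cultured microglia already showed part of the TGFb1 response at 0 h. Of the genes that rose with TGFb1 in macrophages, 67.8% and 65.7% were higher in microglia at 0 h, against 30.8% and 32.3% of those that fell, with the level taken from either macrophage library and the change from the other. The difference of 35.2 points, the mean of both, had the predicted direction. Of all genes 54.9% and 55.3% were higher in microglia at 0 h, so that most of it came from the genes that fell. Yet the test cannot decide the hypothesis. A gene's level in macrophages at 0 h also bears on whether it can be called as a rise or a fall. Neural genes such as Ncan were in the microglia cultures too, so a higher level there need not come from microglia. The call of 719 genes between monocytes and microglia in a fit of their 16 libraries was also set against 99 other splits of these libraries, a test planned before. Of the 100 splits 1 had as many genes, the real one, and the highest other had 221 and the median 0. The other splits mix the cell types, which widens the spread, so they call few genes by construction. The test cannot tell cell type, neutrophil RNA and depth apart.

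Markers of cell types other than neutrophils passed in few cases in vivo between monocytes and microglia. Lymphocyte markers (0 of 5 called, 0 alone, camera adjusted p = 0.66) and dendritic cell markers (2 of 5 higher, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.49) did not shift. Lists too short for a test gave 2 of 4 border macrophage markers higher in monocytes and 0 of 3 oligodendrocyte, 2 neuron, 2 endothelial, 1 fibroblast and 3 erythroid markers changed in limma, with 1763 genes at an unadjusted p under 0.05 in this comparison. Single libraries differed in erythroid RNA, which made up 0.290% of the total in microglia 1 h replicate 1, 0.346% in 16 h replicate 2 and 0.440% in day 1 replicate 2, against 0.00139 to 0.0165% in the other 10 microglia libraries and 0.158% in monocytes day 1 replicate 1. These 3 microglia libraries are those whose omission ended most named calls at their times (5 of 6, 18 of 19 and 14 of 22).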
